A study of Mus musculus with 4 samples.

How the data were processed

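Total RNA was taken with Trizol from brains of C57BL/6 mouse embryos at embryonic day 15, and 2 ug per sample entered the libraries, per the labels' protocols. The samples were placed in the WT or the FOXM1f/+;Nestin-Cre group by the genotype label. The series' design text speaks of triplicates, whereas 4 samples are listed, 2 per group. Reads were processed with Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 on a genome given as mm9, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so values of paralogs, pseudogenes and overlapping or antisense genes are uncertain. The coordinates in the table match GRCm38 instead. Of 20388 gene identifiers found in GENCODE release M21, 18699 (91.7%) had the same start and end, and 33 further identifiers were not in it.

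The authors' table gives, per the file headers, 1 column of raw read counts and 1 column of normalized values for each genotype. The deposited normalized values are CPM: each is the count times a constant per column, and the authors entered a count of 0 as 0.5 reads. The authors' fold change is the ratio of the normalized columns, FOXM1f/+;Nestin-Cre over WT, and their log2 column is its logarithm. The deposited p-values and adjusted p-values compare 1 column with 1 column, and the test behind them is not given in the sources used here. Genes with fewer than 2 reads in all were absent from the table. The totals behind the CPM were 17859653 and 17547268 reads, 3000 and 3563 more than the table holds for the transgenic and the WT column. A column could be matched to a group and to no sample, so how the 4 samples relate to the columns is unknown.

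Before the data were examined, the comparison was planned with edgeR's quasi-likelihood test on 4 libraries and with camera on gene lists. With 1 column per genotype there are no replicates, and none of these tests was run. The comparison was made on the authors' CPM instead, for genes with a mean of at least 1 CPM. Each ratio has an exact conditional (Clopper-Pearson) 95% interval for the ratio of 2 Poisson rates. A value at 0 reads is given as a bound against a floor of 3 counts per library, which is 0.168 CPM in the transgenic and 0.171 CPM in the WT library; such a bound leaves out the counting error of the other library. Intervals of read ratios and floors cover counting error only. Reads without molecular identifiers are not independent molecules, and the spread between animals is not measured. The interval of a list median is an order-statistic interval over its member genes, in short lists their full range. That of a difference between medians comes from 10000 bootstrap draws of genes. Both treat genes as independent and measure the spread among genes. Genes were called higher or lower in counts from a ratio of at least 2-fold. A share of reads has an exact Clopper-Pearson interval.

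The 31 gene lists were fixed before the data were examined, and each list is described by the median log2 ratio of its members and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Named genes follow a rule written at the same time, which was adapted once it was seen that there was 1 column per genotype. Foxm1 is always named, then the 10 genes with the largest ratio in each direction, leaving out predicted and unnamed genes. From each list up to 4 members are named whose interval excludes 1, by the size of the difference relative to its counting error; where no interval excludes 1, up to 2 members of highest mean CPM could be named. Some genes that the rule takes are not reported here. Further lists (choroid plexus epithelium, motile cilia, X-linked genes that escape inactivation, embryonic and adult globins) were made after ratios had been seen, and gene ontology terms from the table were ranked after that as well.

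Analyses were run in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, figures were drawn with Matplotlib 3.10.9, and scaling factors were computed in R 4.3.3 with edgeR 4.0.16. The alternatives were scaling by TMM or RLE factors, no expression minimum, at least 1 CPM in both libraries, a mean of at least 10 CPM, a fold of at least 1.5, a counting interval on one side of 1, and leaving out sex-linked, plexus, cilia and erythroid genes. The procedure was tested on simulated data for the FOXM1f/+;Nestin-Cre against WT comparison, with counts drawn for 14557 genes from the libraries' own means. The intervals held the simulated ratio for 95.6% of these genes. Of genes simulated at 3-fold and 6-fold, 100% were called at least 2-fold in the right direction, and 2.99% of those simulated at 1.5-fold. Of unchanged genes, 0.237% were called. Of 200 unchanged lists, 5.5% lay outside the central 95% of random lists. The counts were drawn with counting error alone, without spread between animals, and the unchanged lists were random genes. These rates thus follow from the set-up and are no error rates for a comparison of genotypes.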

Results

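Brains of mouse embryos at embryonic day 15 were profiled by RNA sequencing in wild type (WT) animals and in animals labelled FOXM1f/+;Nestin-Cre, both on the C57BL/6 strain. FOXM1 is a transcription factor that drives genes of the later cell cycle, and the series' title names the human gene. Nestin-Cre is a Cre recombinase driver that is active in neural progenitors. GEO lists 4 samples, 2 per genotype, while the table analysed here holds 1 column of read counts for each genotype. The columns name a genotype and not a sample, and it is not stated whether a column is 1 embryo or a pool. The titles of the 2 samples labelled WT name different alleles, nestin for 1 and foxm1 for the other, and which of them the WT column holds is unknown. The ratios may thus be against a control that carries either allele. The columns are called the transgenic library and the WT library here. The transgenic library held 17856653 reads and the WT library 17543705 reads, over 20421 genes. Every difference given here is between these 2 libraries and has no replicate check. Intervals of read ratios and of shares of reads are 95% exact intervals that cover counting error only. Those of list medians, and of differences between medians, reflect the spread among genes taken as independent.

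The first question was whether the gene named by the genotype differed. Mouse Foxm1 (ENSMUSG00000001517; chromosome 6, 128362967 to 128376146, GRCm38) had 1289 reads in the transgenic library and 1139 in the WT library. That is 72.2 against 64.9 CPM, a ratio of 1.11 (1.03 to 1.21). The genotype label does not say how the allele was built, and no value here measures a human gene. Reads of a human transgene would reach the mouse gene only where the sequences are alike. The log2 ratio of Foxm1, 0.15, also lay below the median of the G2/M and mitosis genes described below, 0.34. The value is therefore at most a weak check of the labels.

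The libraries differed in sex-linked genes. Xist, the RNA that coats the inactive X chromosome, had 9628 reads in the transgenic library and 5 in the WT library. The Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty had 0 reads in the transgenic library, against 1266, 773, 484 and 202 in the WT library. Against the floor of 3 counts in the transgenic library, they were at least 430-, 262-, 164- and 68.5-fold lower. These 4 genes and Xist were the tested members of the sex-linked list, with 1 interval above 1 and 4 below. The genotypes were therefore read in libraries of different sex content, and each difference below is also a difference between those.

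Among 14557 genes with a mean of at least 1 CPM, 76 were at least 2-fold higher and 266 at least 2-fold lower in the transgenic library. Across genes, which are not independent replicates, the log2 CPM of the libraries had a Pearson r of 0.980. The median log2 ratio was -0.01, with a 5th percentile of -0.60 and a 95th percentile of 0.43. Of the 2-fold genes, 34 of the higher and 52 of the lower had predicted or unnamed symbols. Counts of this kind compare 2 libraries, and they varied with the expression minimum.

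After Xist, the named genes with the largest ratios were Capn11, a calpain protease (87 against 4 reads), and Eno1b, an enolase (1827 against 277). Eno1b was 6.48-fold higher (5.71 to 7.38), while Eno1, a near-identical gene with which reads can be shared, had a log2 ratio of -0.07 (-0.11 to -0.04). The embryonic beta globin Hbb-y followed at 6.29-fold higher (5.72 to 6.92), with 3194 against 499 reads. The pseudogene Eif3s6-ps2 had 36 against 6 reads and Masp2, a complement protease, 54 against 10. The embryonic globin Hbb-bh1 had 37 against 8 reads. Mybpc1, a muscle myosin-binding protein, had 30 against 8 and Enpp3, an ectonucleotidase, 29 against 8.

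At the other end, beside the Y-linked genes above and Erdr1 (0 against 601 reads, at least 204-fold lower), Slco1a4, an organic anion transporter, had 0 against 39 reads and was at least 13.2-fold lower. Guca2b, a guanylate cyclase activator, had 0 against 36 reads and was at least 12.2-fold lower. Ttr, the thyroid hormone carrier made in the choroid plexus, had 177 reads in the transgenic library and 11255 in the WT library, 64.7-fold lower (55.8 to 75.5). Myo7a, an unconventional myosin, had 7 against 319 reads and was 46.4-fold lower (22.3 to 116). Clic6, a chloride channel of the plexus, had 9 against 407 reads and was 46.0-fold lower (24.0 to 101).

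**Figure D1:**
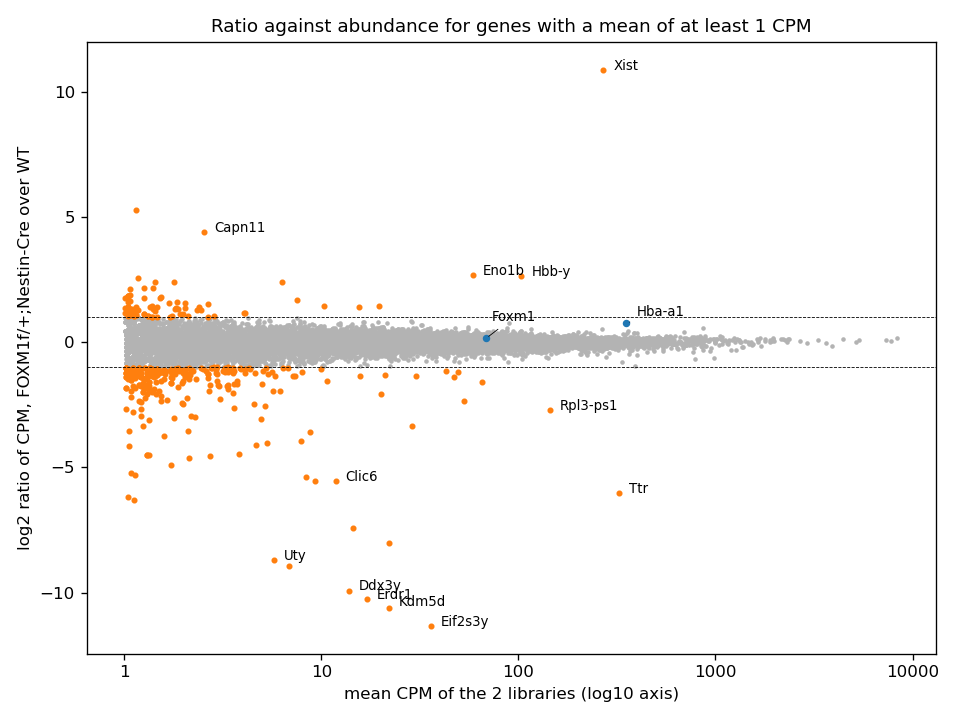
Each point is 1 gene with a mean of at least 1 CPM, with its mean CPM on a log10 x axis and the log2 ratio of the transgenic over the WT library on the y axis. Dashed lines mark 2-fold, and orange points lie beyond them (76 higher and 266 lower); Foxm1 and Hba-a1 are blue.

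Genes of dividing cells were higher in the transgenic library. In the list of G2/M and mitosis genes, all 33 members had ratios above 1, and 32 had intervals wholly above 1. The list's median log2 ratio was 0.34, above all 10000 random lists matched on expression, given as a description of these libraries. Top2a, which untangles DNA strands, had 261 against 203 CPM, 1.29-fold higher (1.23 to 1.34). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, was 1.31-fold higher (1.24 to 1.39), and the mitotic cyclin Ccnb1 and its kinase Cdk1 1.37-fold (1.28 to 1.46) and 1.35-fold (1.26 to 1.46). The G1/S and DNA replication list had 23 of 24 intervals above 1 and 1 spanning it, with a median of 0.33, above all random lists. In it, Pcna, the sliding clamp of DNA replication, had 267 against 218 CPM, 1.22-fold higher (1.17 to 1.28). The replicative helicase subunits Mcm3 and Mcm2 were 1.38-fold (1.28 to 1.48) and 1.33-fold (1.24 to 1.42) higher.

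Progenitor genes were higher too. The apical radial glia list had a median of 0.21, above all random lists, with 13 of 20 intervals above 1, none below and 7 spanning 1. Vim, an intermediate filament of radial glia, had 793 against 599.6 CPM, 1.32-fold higher (1.29 to 1.36). Fabp7, a fatty acid binding protein of the same cells, was 1.19-fold higher (1.16 to 1.22), and the filament Nes and the inhibitor Id4 were 1.23-fold (1.19 to 1.28) and 1.26-fold (1.20 to 1.32) higher. The list of basal intermediate progenitors had a median of 0.29, above all random lists, with 12 of 15 intervals above 1, 2 below and 1 spanning 1. The proneural factor Neurog2 was 1.24-fold higher (1.19 to 1.30) and the stress response gene Gadd45g 1.37-fold (1.28 to 1.46). By contrast, the outer radial glia markers had a median of -0.04, at percentile 30.1 of the random lists, with 2 of 12 intervals above 1, 5 below and 5 spanning 1. With a mean of at least 10 CPM, their median was -0.15 at percentile 1.88, below the central 95%. Tnc, an extracellular glycoprotein, was 1.30-fold lower (1.20 to 1.40) and the transporter Slco1c1 1.91-fold lower (1.53 to 2.38), while Ttyh1 was 1.14-fold higher (1.08 to 1.20).

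Genes of maturing neurons were lower in the transgenic library. The synaptic and activity list had a median of -0.24, below all random lists, with 16 of 19 intervals below 1, none above and 3 spanning 1. Camk2b, a calcium-dependent kinase of synapses, had 175 against 243 CPM, 1.39-fold lower (1.32 to 1.45). The glutamate receptor subunits Grin2b and Gria1 were 1.41-fold (1.31 to 1.52) and 1.30-fold (1.23 to 1.38) lower. The scaffold Shank1 was 1.19-fold lower (1.13 to 1.24). Upper-layer cortical neuron genes had a median of -0.23, at percentile 0.02, with 8 of 11 intervals below 1, 1 above and 2 spanning 1. The homeobox gene Cux2 was 1.27-fold lower (1.18 to 1.35). General neuronal genes had a median of -0.10, at percentile 0.745, with 11 of 15 intervals below 1, 1 above and 3 spanning 1. The microtubule-binding protein Mapt had 827 against 1042 CPM, 1.26-fold lower (1.23 to 1.29).

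Other neuronal lists lay nearer the rest of the genes. Deep-layer neuron genes had a median of -0.10, at percentile 3.78, with 1 of 11 intervals above 1, 4 below and 6 spanning 1. General neuronal genes had a like median, -0.10, but their list was longer and its random band narrower. The lower end of the band was -0.08 for general neuronal and -0.11 for deep-layer genes, so the medians do not set these lists apart. Sox5 was 1.15-fold higher (1.09 to 1.22) and Crym, a thyroid hormone binding protein, 1.35-fold lower (1.15 to 1.58). Ganglionic eminence and interneuron genes had a median of -0.03, at percentile 23.2, with 6 of 19 intervals above 1, 5 below and 8 spanning 1. The homeobox gene Dlx2 was 1.13-fold higher (1.07 to 1.18) and Gad1, which makes GABA, 1.17-fold lower (1.09 to 1.25). Cajal-Retzius genes had a median of 0.08, at percentile 88.4, with 4 of 10 intervals above 1, 3 below and 3 spanning 1. Ndnf was 1.34-fold lower (1.10 to 1.63) and Nhlh2 1.17-fold higher (1.05 to 1.31). Diencephalon genes had a median of 0.04, at percentile 70.8, with 1 of 8 intervals above 1 and 7 spanning 1; the homeobox gene Lhx9 was 1.70-fold higher (1.46 to 1.98). Of the midbrain and hindbrain list, 1 gene passed the expression minimum and no median is given.

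The lists of oligodendrocyte precursors and astroglia had medians below the central 95% of random lists. Oligodendrocyte precursor genes had a median of -0.71, below all random lists, with 4 of 6 intervals below 1 and 2 spanning 1. Pdgfra, the growth factor receptor of these precursors, had 87 against 195 reads, 2.28-fold lower (1.76 to 2.97), and Gpr17 was 2.26-fold lower (1.51 to 3.42). Astroglia genes had a median of -0.40, at percentile 0.01, with 4 of 7 intervals below 1 and 3 spanning 1. The lipid carriers Clu and Apoe were 1.56-fold (1.40 to 1.73) and 1.32-fold (1.22 to 1.42) lower. Microglia genes had a median of -0.31, at percentile 3.95 (2.27 with at least 1 CPM in both libraries, below the central 95%), with 4 of 11 intervals below 1 and 7 spanning 1, among them the purine receptor P2ry12, 2.01-fold lower (1.40 to 2.94).

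Some genes of the choroid plexus, vessels and meninges had intervals below 1. The list of choroid plexus and cortical hem genes had a median of -0.33, at percentile 1.36, with 5 of 11 intervals below 1 and 6 spanning 1. The median depended on the expression minimum, at -0.80 without one and -2.81 with a mean of at least 10 CPM, and the list lay at percentile 6.44, inside the central 95%, with at least 1 CPM in both libraries. Beside Ttr and Clic6, the folate receptor Folr1 had 11 against 175 reads, 16.2-fold lower (8.83 to 33), and the homeobox gene Msx1 25 against 82. Endothelial genes had a median of -0.22, at percentile 0.900, with 1 of 11 intervals above 1, 3 below and 7 spanning 1 (median -0.12 at percentile 6.29, inside the central 95%, with a mean of at least 10 CPM), and the receptor Tek was 1.65-fold lower (1.23 to 2.22). Pericyte and meningeal genes had a median of -0.37, at percentile 0.140, with 1 of 11 intervals above 1, 6 below and 4 spanning 1, and the collagen Col1a2 was 2.54-fold lower (1.93 to 3.38). Erythroid genes had a median of 0.91 (members from -0.12 to 2.65), above all random lists, with 5 of 8 intervals above 1 and 3 spanning 1. The median was 0.45 with at least 1 CPM in both libraries. Hba-x, an embryonic alpha globin, was 2.62-fold higher (2.17 to 3.18). Of the adult alpha globins, Hba-a1 was 1.70-fold higher (1.64 to 1.76), while its near-identical copy Hba-a2 had 175 against 184 reads, a log2 ratio of -0.10 (-0.40 to 0.21). Reads of the pair can be split between the copies in counting, so both values are uncertain.

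Among the signalling lists, those of Lin28 and let-7 and of Wnt targets had medians above the central 95% of random lists, and neither kept that place at every expression minimum. The Lin28 and let-7 list had a median of 0.24, at percentile 98.8, with 3 of 5 intervals above 1 and 2 spanning 1. It lay inside the central 95% of random lists without an expression minimum (percentile 97.3) and with a mean of at least 10 CPM (95.9). Hmga2, a chromatin protein of fetal progenitors, was 1.56-fold higher (1.25 to 1.95) and Igf2bp1 1.20-fold higher (1.11 to 1.31). Wnt targets had a median of 0.19, at percentile 97.9, with 3 of 7 intervals above 1 and 4 spanning 1 (median 0.11 at percentile 90.2, inside the central 95%, without an expression minimum, and just inside it with at least 1 CPM in both libraries), and Lef1 was 1.47-fold higher (1.20 to 1.80). Notch targets had a median of 0.11, at percentile 84.8, with 2 of 6 intervals above 1 and 4 spanning 1 (median 0.28, above the central 95%, with a mean of at least 10 CPM), and Hes5 was 1.49-fold higher (1.27 to 1.74). Hedgehog targets had a median of 0.06, at percentile 68.0, with 1 of 3 intervals above 1 and 2 spanning 1, and Gli1 was 1.29-fold higher (1.02 to 1.63). Matrix and integrin genes had a median of 0.05, at percentile 86.2, with 6 of 18 intervals above 1, 2 below and 10 spanning 1, and the laminin Lama1 was 1.66-fold higher (1.38 to 2.00).

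Lists of stress and sample state had medians within the central 95% of their random lists at the main expression minimum. Immediate early genes had a median of -0.04, at percentile 42.8, with 1 of 10 intervals above 1, 2 below and 7 spanning 1. In it, Jun was 1.19-fold higher (1.11 to 1.28) and Nr4a1 1.48-fold lower (1.20 to 1.83). Hypoxia and glycolysis genes had a median of 0.07, at percentile 91.0, with 4 of 15 intervals above 1, 3 below and 8 spanning 1, and Pgk1, a glycolytic kinase, was 1.17-fold higher (1.12 to 1.21). Targets of p53 had a median of -0.05, at percentile 29.0, with 2 of 12 intervals above 1, 3 below and 7 spanning 1, and the death gene Bbc3 was 1.37-fold lower (1.21 to 1.56). Interferon response genes had a median of 0.17, at percentile 90.2, and all 8 intervals spanned 1 (median 0.29, just above the central 95%, without an expression minimum); Stat2 had 502 against 490 reads and Ifit2 131 against 115. Mitochondrially encoded genes had a median of 0.08, at percentile 90.1, with 6 of 11 intervals above 1, 2 below and 3 spanning 1. Their share of reads was 2.38% (2.37 to 2.38) in the transgenic and 2.27% (2.26 to 2.27) in the WT library, by exact Clopper-Pearson intervals.

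**Figure D2:**
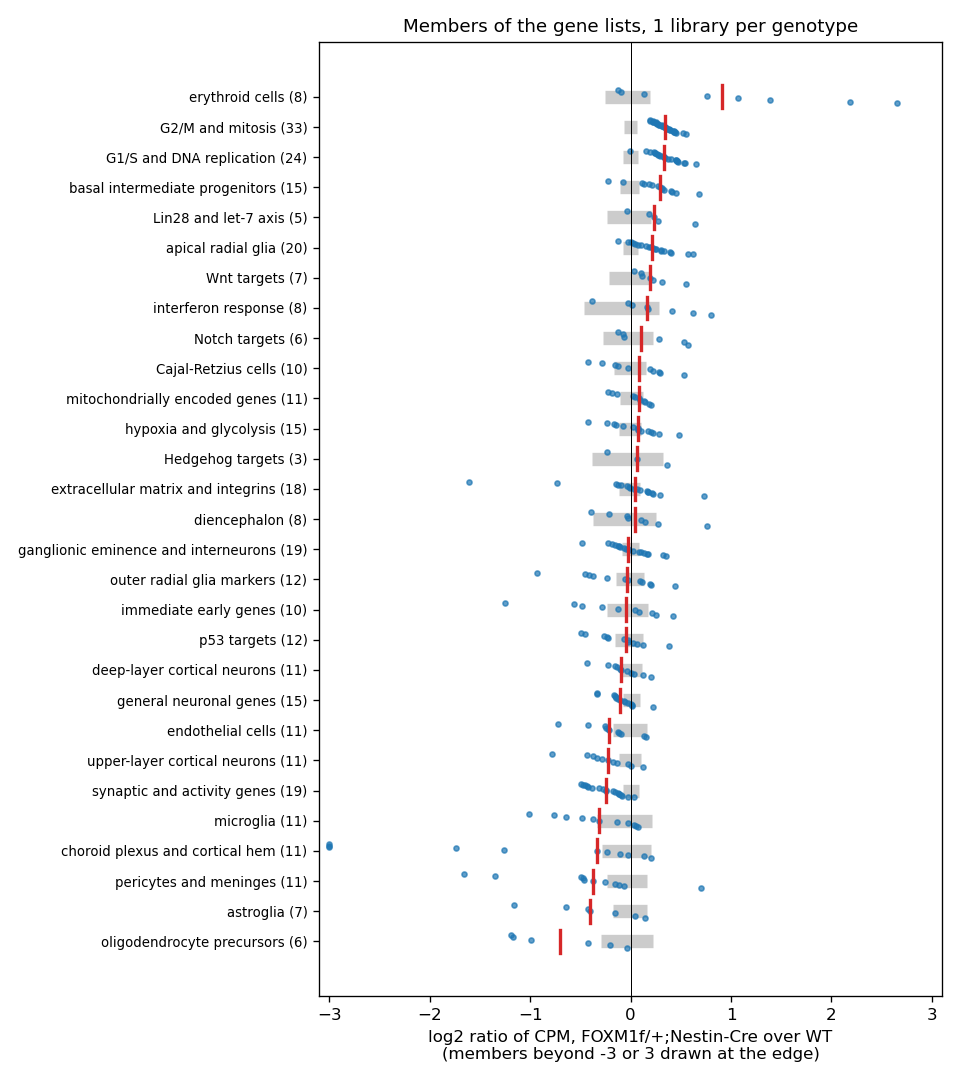
Each dot is 1 tested gene of a list fixed before the data were examined, placed by its log2 ratio of CPM, transgenic over WT library, on the x axis; the number of tested genes follows the list's name, dots beyond -3 or 3 are drawn at the edge, and the sex-linked list is not drawn. Red bars are list medians and grey bands hold the central 95% of medians of random lists matched on expression, so that the G2/M median of 0.34 and the synaptic median of -0.24 lie outside their bands.

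Of 30 lists with at least 3 tested genes, 7 had medians above and 9, the sex-linked list among them, below the central 95% of their random lists. Chance gives 1.5 in all only for independent lists of independent genes. The random lists leave out that genes of a list can move together, so the 1.5 is no measure of chance for these lists. In the authors' deposited table, 1931 genes were marked as significant, 642 up and 1289 down. The smallest fold among the marked genes of the authors' deposited table was 1.5 and the largest p-value 0.0496. Genes with few reads in either library and those with the smallest p-values were left out of the next comparison. For 97.4% of the 14738 genes that remained, the p-value in the authors' deposited table lay within 0.1 on the log10 scale of one computed from counting error alone. Those p-values compare the 2 libraries, not the genotypes.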

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

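The alternatives with a mean of at least 10 CPM, a fold of at least 1.5, a counting interval on one side, TMM scaling and the omission of gene groups were chosen after the data were seen. The counts of genes at least 2-fold apart (76 higher and 266 lower) moved with the expression minimum and the fold, by construction. Without a minimum they were 975 and 1946. With at least 1 CPM in both libraries they were 25 and 108, with a mean of at least 10 CPM 6 and 20, and at 1.5-fold 369 and 762. They stayed within 1.5 times the main counts under TMM and RLE scaling (78 and 261 under each), with intervals on one side (75 and 262), and without sex-linked, plexus, cilia and erythroid genes (71 and 230). Scaling by TMM or RLE shifted every log2 ratio by 0.02 or 0.03, and Foxm1 was then at 0.17 or 0.18. Through that shift, Tubb3, a neuronal tubulin, reversed from -0.02 to 0.0039 under RLE scaling, and 7 values of mitochondrially encoded genes left their counting intervals. List genes with intervals spanning 1 changed sign too, E2f1 and Syt1 among them. Of the list medians, 4 near 0 changed sign: without a minimum, outer radial glia markers to 0.04, diencephalon genes to -0.03 and Hedgehog targets to -0.09, and with a mean of at least 10 CPM, Cajal-Retzius genes to -0.08. Which genes entered differed, by construction. Percentiles that crossed the central 95% stand beside their lists. The planned DESeq2, limma-voom, fry, camera, adjusted p thresholds and leaving out of single libraries were not run, nor was the comparison between WT libraries, since each genotype has 1 column. No paired analysis was possible because each genotype has 1 column. Depth limits the low genes: 1 read is 0.0560 CPM in the transgenic and 0.0570 CPM in the WT library.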

Other observations

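The tests chosen only after the results were seen are those of scaling, of a G2/M-only difference, of age, of sex and of the choroid plexus, and those of scaling, plexus tissue, non-neural cells and the hem were redefined after a first result. The tests of length and GC content were set before their results were seen. That of Rpl3 was set before the summed ratio was seen, but the pair was chosen after its read counts had been seen. Gene ontology terms were also ranked after the ratios had been seen. Some of the extreme terms name the same processes as the fixed cell cycle and synaptic lists, and the genes they share were not counted. Of 1666 terms with 15 to 200 tested genes, 24 had medians above and 17 below all random lists. Genes annotated to the cytosolic small ribosomal subunit had a median log2 ratio of 0.14 over 91 entries, with 74 above 0. Whether these entries include near-identical copies that share reads was not examined. Genes of the spliceosomal complex had a median of 0.10 over 90 genes, with 66 above 0. Genes of the presynaptic active zone had a median of -0.17 over 24 genes, with 3 above 0, and those of long-term synaptic potentiation -0.18 over 35 genes, with 6 above 0. Terms share genes and are not independent.

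X-linked genes known to escape inactivation were higher in the transgenic library, with a median log2 ratio of 0.42 and 4 of 4 intervals above 1, beside a log2 ratio of Xist of 10.9. Kdm6a, a histone demethylase, had 646 against 430 reads and Eif2s3x, a translation factor, 1806 against 1316. Embryonic globins had a median of 2.18 over 3 genes and adult globins 0.18 over 4, with 2 intervals above 1 (Hba-a1 and Hbb-bs) and 2 spanning 1 (Hba-a2 and Hbb-bt). Over 505 tested genes of the X chromosome, the median log2 ratio was -0.03, against -0.01 for the other genes. Lin28a, an RNA-binding protein of early progenitors, had 9 reads in the transgenic library and 0 in the WT library, and lay under the expression minimum. Gt(ROSA)26Sor, a locus often used for inserted transgenes and chosen here after its value was seen, had 515 against 184 reads, a log2 ratio of 1.46 (1.21 to 1.71). Its neighbour Thumpd3, which overlaps it on the other strand, had a log2 ratio of 0.03 (-0.16 to 0.23), and its neighbour Setd5 -0.15 (-0.22 to -0.07). The strand setting of the counting is not given, and the source of the difference was not tested.

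Genes of the cell cycle were higher and synaptic genes lower in the transgenic library, with medians of 0.34 and -0.24. Gene length and GC content do not account for all of this. After removing the median of genes of like length and GC, the medians were 0.32 (0.29 to 0.37) and -0.17 (-0.33 to -0.07). The synaptic difference shrank with this correction, so part of it may go with length or GC. A single scaling factor per library moves all genes alike, so it cannot set the medians 0.59 apart (0.43 to 0.73). The higher values were not limited to G2/M genes, as the G2/M median exceeded the G1/S median by 0.00996 (-0.10 to 0.07). These medians were known when both comparisons were chosen, so the comparisons only describe the libraries. An earlier age of the transgenic embryos stays open: relative to the adult globins, Hbb-y had a log2 ratio of 2.16 (2.02 to 2.29), but every globin ratio had been seen before that test was chosen, so its outcome was known and it decides nothing. Sex cannot be told apart from genotype, with Xist at 10.9 in 1 column per genotype, and the genotype itself stays open as untested.

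Ttr, Clic6 and Folr1 of the choroid plexus were far lower in the transgenic library. Otx2, on the same list of choroid plexus and cortical hem genes, was not, with a log2 ratio of -0.11. A list of 30 epithelium markers assembled afterwards had a median of -2.81, but 18 of its members had been picked or known with their ratios in view, and the 17 of these that were tested had a median of -4.02. The 12 members whose ratios had not been seen, 9 of them tested, had a median of -0.31 (-0.78 to 0.07), with 5 intervals below 1 and none above, so a smaller share of plexus tissue, as from dissection, may or may not be the source; several of these genes are also expressed elsewhere in the brain. The endothelial, microglial and pericyte and meningeal medians were -0.22 (-0.42 to 0.13), -0.31 (-0.76 to 0.05) and -0.37 (-1.35 to -0.06). All lay far above -3.14, the highest upper bound of Ttr, Clic6 and Folr1, so these lists were not lowered by a like fold. Those 3 genes were taken for their low ratios and the test was redefined after a first result. It therefore decides nothing about a smaller loss of non-neural cells. Loss of the hem stays open, as 7 hem genes had a median of -0.24 and ranged from -1.74 to 0.20. The low end was Msx1 (-1.74) and Lmx1a (-1.26), which entered the test when it was redefined. The other hem genes ranged from -0.33 (Rspo1) to 0.20 (Rspo3), so the verdict rests on Msx1 and Lmx1a. Motile cilia genes, with a median of -1.24 over 21 tested, lay at -2.42 for 11 tested members seen beforehand and at -0.08 (-0.92 to 0.13) for 10 not seen, and whether selection or a closer tie of the former to the tissue sets them apart was not tested.

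Rpl3, a ribosomal protein gene, had 18480 against 12137 reads (log2 ratio 0.58), while its pseudogene Rpl3-ps1 had 688 against 4387 (-2.70). Reads shared between near-identical copies are a candidate explanation. The pair was chosen after its values had been seen, and its summed ratio is fixed by those values. Summed, the pair had a log2 ratio of 0.19, inside the range from 0.06 to 0.23 that holds the central 90% of 74 other ribosomal protein genes, while Rpl3 alone lay outside it. Why the split differed between the libraries was not tested, and a sequence difference between the animals stays open. No biological explanation was tested for this pair.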
